A study of Homo sapiens with 4 samples.

How the data were processed

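The data were m6A-seq libraries of a line that the series design and the growth protocol call MDA-MB-231Br, a brain-seeking derivative of the MDA-MB-231 breast cancer line, and that the cell line label calls MDA-MB-231. The extraction protocol speaks of embryos, which conflicts with both, and the sources used here do not settle this. Per the labels' protocols, poly(A) RNA was purified, sonicated and immunoprecipitated with an antibody against N6-methyladenosine (m6A), and stranded mRNA libraries were made from the immunoprecipitate (IP) and from input. The labels gave 2 input and 2 IP libraries, numbered 1 and 2, and did not say whether these came from separate cultures. The submitters' processing notes named HISAT2, HOMER and the GRCh38/hg38 build, with no version or role, and the method of peak calling, the library totals and any pooling of replicates were not given in the sources used here.

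A single peak table was used. Per the file headers it held, for each peak, a gene symbol, coordinates, a transcript region, an input read count, an IP read count, a p-value, a false discovery rate (FDR) and a window score. The deposited read counts were whole numbers, 1 for IP and 1 for input, with no replicate number, so they were treated as the authors' pooled counts. The p-value and FDR were the authors' own, with FDR values up to 0.1 and below the p-value in 19.8% of peaks, so they were described and not used as a test. The authors' score was at least 1 in the whole table and infinite in 902 peaks. Every listed peak had at least 5 IP reads. The table therefore held only windows that had passed the authors' thresholds, and a gene without a peak may be unmethylated, weakly expressed or below those thresholds.

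Of 27855 entries, 177 repeated the gene and coordinates of another, and 27678 peaks were kept. Genes were matched to GENCODE release 29 (GRCh38) by symbol, chromosome and strand for 27434 peaks. For 183 the match came through other symbols in a gene name list or through RefSeq synonyms. Another 55 peaks, whose 12 symbols had been turned into dates, were matched by coordinates, and 6 peaks were left unmatched. Peaks were placed on spliced transcripts by requiring both ends in exons and a spliced length that was a multiple of 10 nt, which gave 27154 peaks (98.1%) with a sequence. On the longest coding transcript of each gene, 96.6% of 16613 spliced peaks had such a length, where 10% would by chance, which ties the coordinates to this build. Start and end are printed 1-based as in the table. The authors' region column equalled the region of the peak's genome-left end in 97.5% of peaks and that of its midpoint in 86.5%, so in minus-strand genes it reads the 3' end of the peak.

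The design fixed before the data were examined named the authors' fold, or else their score, as the measure of enrichment. The table held no fold, and the score was almost unrelated to the reads (Spearman rho 0.0687 with the read ratio across peaks, which are not independent replicates). The main measure was therefore log2((IP + 1)/(input + 1)) of the deposited read counts, with a pseudocount of 1, and the score was run as an alternative. Read ratios given with reads were IP over input without a pseudocount, with an exact Clopper-Pearson interval at the 95% level from the share of IP reads. With 0 input reads the ratio was given as a lower bound against a floor of 3 counts. Peaks with at least 4 IP reads per input read were taken from the reads without a pseudocount. This class takes in all 545 peaks with 0 input reads, since every listed peak had at least 5 IP reads. For such peaks the lower bound against the floor of 3 counts can lie below 4. Intervals and floors cover counting error only. Since library totals were not used, a ratio of 1 does not mark the absence of enrichment, and ratios were compared only between peaks of this table.

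Region shares were given with exact Clopper-Pearson intervals, and differences of median log2 ratio between regions with a two-sided permutation test of 100000 resamples, Benjamini-Hochberg adjusted over the 3 pairs, with intervals from 300 resamples of genes. Distance to the stop codon was the share of midpoints within 200 nt of it, against 100 sets of windows of the same length drawn at random in the same transcripts. DRACH (D is A, G or T; R is A or G; H is A, C or T), the consensus of the m6A methyltransferase, was counted on the transcribed strand against 100 dinucleotide-shuffled copies of each peak. The smallest two-sided p that 100 draws allow is 0.0198, and that of the permutation test is 1e-05. Peaks and genes are not replicates, so these p-values describe the table and not the spread between libraries. Listed peaks often overlap: 27678 fall to 14061 when those closer than 100 bp are merged. Random positions, shuffled copies and control windows were drawn for each peak separately. The p-values of stop codon distance and motifs may therefore be too small.

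The 24 gene lists were fixed before the data were examined: study targets, metastasis mediators, m6A writers and erasers, m6A readers, epithelial to mesenchymal transition (EMT), EGFR and MAPK pathway, angiogenesis, cell junctions, sialyltransferases, integrins with matrix and proteases, immediate early and short-lived regulators, TGF-beta and SMAD, Hippo pathway, chromatin regulators, housekeeping, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, zinc finger genes, replication-dependent histones, mitochondrially encoded genes, long non-coding RNA, and markers of luminal breast, brain, and immune and stromal cells. The share of members with a peak was set against the other protein-coding genes of GENCODE release 29 (19907 in all, 36.5% with a peak) with Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 23 lists of protein-coding genes; expression was not measured in that background. For the 18 lists with at least 5 members carrying a peak, the median of the highest log2 ratio per gene and the median number of peaks were set against 10000 random lists of the same size drawn from the 7261 protein-coding genes with a peak, adjusted in the same way. Genes could be named in the text by a rule fixed beforehand, with those left unnamed covered by counts: all members of the study targets, writers and erasers, and readers, up to 4 members of each other list by highest ratio, and the 10 genes with the highest ratio and the 10 with most peaks.

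A reference ratio was fitted for each of the 2766 genes with at least 4 peaks, as the single IP-to-input ratio against which a binomial p of the gene's peaks came closest to the authors' deposited p-value. The random-list, motif, stop codon, median permutation, reference ratio and exact interval steps were tested on simulated data; Fisher's test, the differences within GC bins and the resampling of genes were not. Random lists of 20 genes without a shift passed p of 0.05 in 5.5% of runs, and lists shifted by 1 SD in 92% (7000 simulated genes). The two-sided form was chosen in 99.4% of 500 simulated genes with a two-sided p and in 0.2% of those with a one-sided p. In 5000 simulated sequences with 1 planted site each, DRACH came out at 1.15 times the shuffled copies where the true excess was 1.29-fold, because shuffled copies carry the planted dinucleotides; the comparison is thus conservative. Without a planted site DRACH came out at 0.988 times, so a single set without a signal need not give exactly 1. The simulated bases were independent and equally frequent, so this value is not a baseline for the peaks.

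The planned test of IP against input per peak across libraries, and the overlap of peaks between replicates, could not be made without values per library. Alternatives covered the peak threshold, the merging of peaks closer than 100 bp, 1 peak per gene, own annotation of the midpoint, other distances, motifs and controls, length-matched backgrounds and, chosen after seeing the data, the strand, the score and the fitted reference ratio. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.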

Results

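A line given as MDA-MB-231Br in the series design and growth protocol, a brain-seeking derivative of the MDA-MB-231 breast cancer line, and as MDA-MB-231 in the cell line label was profiled by m6A-seq, in which an antibody against N6-methyladenosine pulls down fragments of poly(A) RNA that are compared with input RNA. The labels gave 2 IP and 2 input libraries, and the peak table held 1 read count of each kind per peak, treated here as pooled. There was therefore no replicate value for any peak, no test across libraries was possible, and the intervals below are exact 95% intervals for counting error. The table listed 27678 peaks in 7269 genes, nearly all of them protein-coding. The peaks held 4917888 IP reads and 4790407 input reads, counted anew in each peak where peaks overlapped. A median peak had 32 IP reads (interquartile range 12 to 100) and 67 input reads (26 to 160).

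Listed peaks covered both RNA regions rich in IP reads and regions poor in them. IP reads outnumbered input reads in 11223 peaks (40.5%), spread over 5364 genes, and at least 4 IP reads stood against each input read in 4761 peaks of 3160 genes. These 4761 peaks include all 545 with 0 input reads, whatever their number of IP reads. At the other end, 8387 peaks (30.3%) had at least 4 input reads for each IP read. The 5' UTR of BASP1, a membrane-bound growth protein of neurons, held 1398 IP and 5 input reads (ratio 279.6, interval 119.5 to 862.5; chromosome 5, 17217560 to 17217809, exon 1). CC2D1A had 646 IP and 4 input reads in its 5' UTR (161.5, 62.8 to 594.5), and SLC25A20, the mitochondrial carnitine carrier, 715 and 5 in exon 1 (143, 60.99 to 442). In the receptor tyrosine kinase ROR1 a 5' UTR peak with 160 IP and 0 input reads gave a ratio of at least 53.3. HSPG2, which encodes the matrix proteoglycan perlecan, had most peaks with 39, ahead of NAV2 with 36, MPRIP with 29, DYNC1H1 with 27, CIC and RRP12 with 26 each, COL4A2 with 25, and SIPA1L3 and UBR4 with 24 each. In HSPG2 IP exceeded input in 11 of the 39, and in ARHGEF11 in 0 of 25. Against a reference ratio fitted to each gene with at least 4 peaks, 58.7% of 19520 peaks lay below it (interval over genes 57.7% to 59.7%); this reference is fitted within the gene and is not a level of no enrichment.

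Transcripts linked to brain metastasis were the study's question, as its title states, and all 4 genes of the study target list carried a listed peak. VEGFA, the main angiogenic growth factor, had 9 peaks, with IP above input in 6. Its highest peak lay in exon 1 on chromosome 6, 43770603 to 43771302, across the start of the coding sequence as annotated, with 1184 IP and 55 input reads (21.5, 16.4 to 28.8). A peak in the 3' UTR of VEGFA (43785343 to 43785442) had 601 and 103 reads (5.83, 4.73 to 7.26), while a coding peak reaching from 43778471 to 43782049 had 42 and 183 (0.230, 0.160 to 0.322). EGFR, the epidermal growth factor receptor on chromosome 7, had 22 peaks, but IP exceeded input in 3 of them: the 5' UTR in exon 1 (55019101 to 55019360; 121 IP and 23 input reads; 5.26, 3.35 to 8.61) and overlapping coding peaks around exons 14 and 15, the higher with 755 and 335 reads (2.25, 1.98 to 2.57). A coding peak in exon 2 of EGFR had 5 IP reads against 487 (0.0103, 0.00332 to 0.0241). Equal read numbers do not mark a level of no enrichment. Against the reference ratio fitted to each gene, 8 EGFR peaks lay above it (reference 0.203). Of the VEGFA peaks, 2 lay above theirs (reference 4). ST6GALNAC5, a brain sialyltransferase, had 1 peak in exon 5 (chromosome 1, 77063191 to 77063350) with 26 IP and 9 input reads (2.89, 1.31 to 7.01). The gap junction gene GJA1 had 1 coding peak in exon 2 (chromosome 6, 121446861 to 121447020) with 19 and 35 reads (0.543, 0.293 to 0.975). For that GJA1 peak the authors' deposited table gave a p of 0.000174 and an FDR of 0.0511. Carrying a peak was more frequent for these 4 genes than for other protein-coding genes (100% against 36.5%; Fisher's exact test, adjusted p = 0.0452), but the list was drawn up from knowledge of the study, which may have picked them on these libraries, so this is not independent evidence. With a background matched on transcript length the adjusted permutation p was 0.105, and among peaks above the median ratio that of Fisher's exact test was 0.163.

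**Figure D1:**
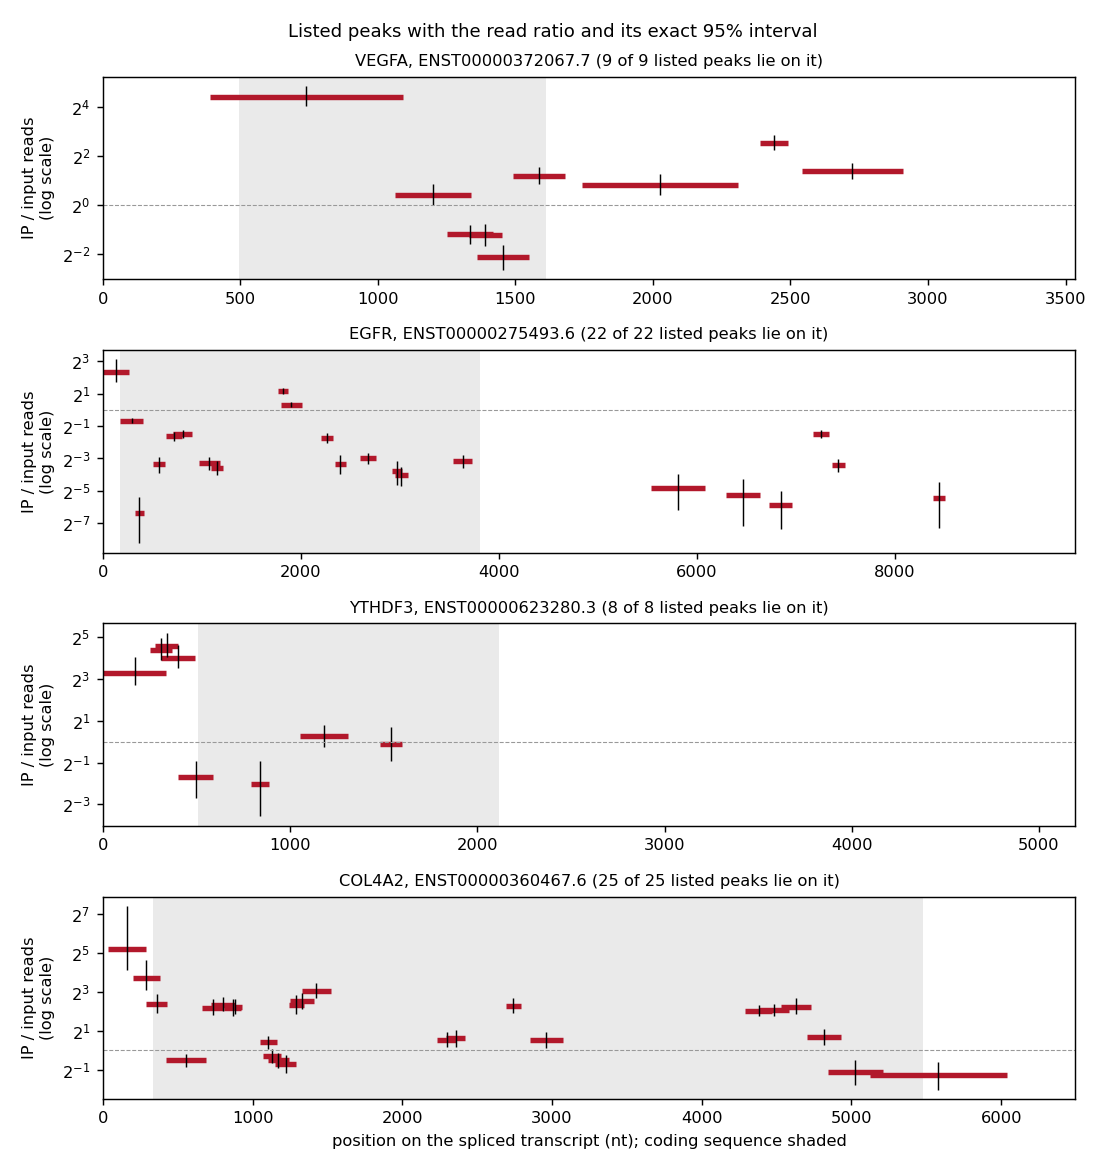
Listed peaks of VEGFA, EGFR, YTHDF3 and COL4A2 on the spliced transcript named in each panel. The x axis is the position in nt with the coding sequence shaded, the y axis the IP-to-input read ratio on a log scale with a pseudocount of 1 (red bars span the peak), vertical lines are exact 95% intervals from the reads, and the dashed line marks equal read numbers; the highest ratios lie at the 5' end in all 4 genes, and most EGFR peaks lie below the line.

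Genes of the m6A machinery themselves carried peaks. Of 13 writers and erasers, 12 had a peak (92.3%, 64.0% to 99.8%; Fisher's exact test, adjusted p = 0.000273), the exception being METTL3, the catalytic methyltransferase. The highest ratio was in the writer subunit ZC3H13, with 714 IP and 12 input reads in coding exon 12 (chromosome 13, 45975502 to 45975831; 59.5, 33.8 to 116). RBM15B followed with 567 and 127 reads (4.46, 3.68 to 5.46), WTAP with 31 and 7 (4.43, 1.91 to 11.9) and RBM15 with 112 and 30 (3.73, 2.48 to 5.79). The demethylase ALKBH5 reached 3.41 (2.10 to 5.76) and VIRMA 2.05 (1.41 to 3.02). METTL14 had 44 and 43 reads (1.02, 0.657 to 1.60), and the demethylase FTO 23 and 57 (0.404, 0.237 to 0.665). ZCCHC4, which methylates ribosomal RNA, reached 2.43 (0.957 to 6.93) and the writer subunit CBLL1 0.875 (0.270 to 2.76). Lowest were the methyltransferases METTL16 (0.286, 0.113 to 0.643) and METTL5 (0.190, 0.112 to 0.309). Among writers and erasers, 3 of 13 had a peak with at least 4 IP reads per input read, a share not different from other genes (Fisher's exact test, adjusted p = 0.734). The highest ratio per gene had a median of 2.13, against 2.83 in random lists (permutation of list membership, adjusted p = 0.906).

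Among the genes of proteins that bind m6A, YTHDF3, PRRC2A and YTHDF2 had high ratios, 5 others had peaks with low ratios and 7 had no listed peak. YTHDF3, the reader in the study's title, had 8 peaks on chromosome 8, and 4 overlapping ones in the 5' UTR had ratios between 10.3 and 24.5. The highest of these joined exons across 63168833 to 63173676, with 662 IP and 27 input reads (24.5, 16.7 to 37.5). In the coding sequence of YTHDF3 the ratios fell between 0.226 and 1.22. YTHDF2 reached 6.70 (5.15 to 8.86) in its 5' UTR with 429 and 64 reads, and PRRC2A 17.8 (15.9 to 19.9) in coding exon 17 with 5907 and 332. The highest ratio was 0.517 (0.386 to 0.688) for YTHDC1, 0.277 (0.203 to 0.373) for IGF2BP2 and 0.130 (0.0781 to 0.205) for RBMX. For ELAVL1 it was 0.645 (0.349 to 1.17), and for IGF2BP3 1.20 (0.719 to 2.02). Against the reference ratio fitted to each gene, 2 RBMX peaks lay above it (reference 0.0442) and 0 IGF2BP2 peaks (reference 1.23). No peak was listed for YTHDF1, YTHDC2, IGF2BP1, HNRNPA2B1, HNRNPC, FMR1 or EIF3A. With 8 of 15 members carrying a peak (53.3%, 26.6% to 78.7%), readers did not differ from other genes (Fisher's exact test, adjusted p = 0.270), nor did their median highest ratio of 0.885 from the 2.78 of random lists (0.803 to 8.25; adjusted p = 0.211).

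Along the transcript, the IP-to-input read ratio was highest at the 5' end. By the authors' region column 17.9% of peaks lay in the 5' UTR (17.4% to 18.3%), 68.3% in coding sequence (67.8% to 68.9%) and 13.8% in the 3' UTR (13.4% to 14.2%). The median read ratio was 2.4 in the 5' UTR, 0.5 in coding sequence and 0.5 in the 3' UTR. On the log2 scale the 5' UTR exceeded coding sequence by 2.26 (2.16 to 2.36, over resampled genes) and the 3' UTR by 2.26 (2.11 to 2.43). Both had an adjusted p of 1.5e-05 from a permutation p of 1e-05, the smallest 100000 resamples can give. With 1 peak per gene, the highest, these differences were smaller, at 1.05 and 1.19. With the log2 score of the authors' deposited table in place of the ratio they were 0.71 and 0.97. For 3' UTR against coding peaks the pooled difference was 0.00 (-0.13 to 0.13; permutation test, adjusted p = 1), but the strands went opposite ways, at -0.39 on the plus and 0.43 on the minus strand, where this column reads the 3' end of the peak. By midpoint it was -0.20, and with the score of the authors' deposited table it was -0.26. Measured at the midpoint, peaks with at least 4 IP reads per input read lay in the 5' UTR in 32.3% of cases (30.95% to 33.7%), against 4.04% (3.62% to 4.49%) for peaks with at least 4 input reads per IP read. Per kb of annotated sequence in genes with a peak there were 1.88 midpoints in 5' UTRs, 1.32 in coding sequence and 0.244 in 3' UTRs. Base composition moved with this: median GC content was 65.5% in 5' UTR peaks, 54.4% in coding peaks and 51.9% in 3' UTR peaks. Without matching, the difference between 5' UTR and coding peaks was 2.08 by midpoint. Within 10 bins by GC content, of about equal peak number, it was 0.43 (0.30 to 0.54), so 20.7% of it remained. Each bin still spans a range of GC content. By midpoints, 14.5% of plus-strand and 11.8% of minus-strand peaks lay in the 5' UTR.

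**Figure D2:**
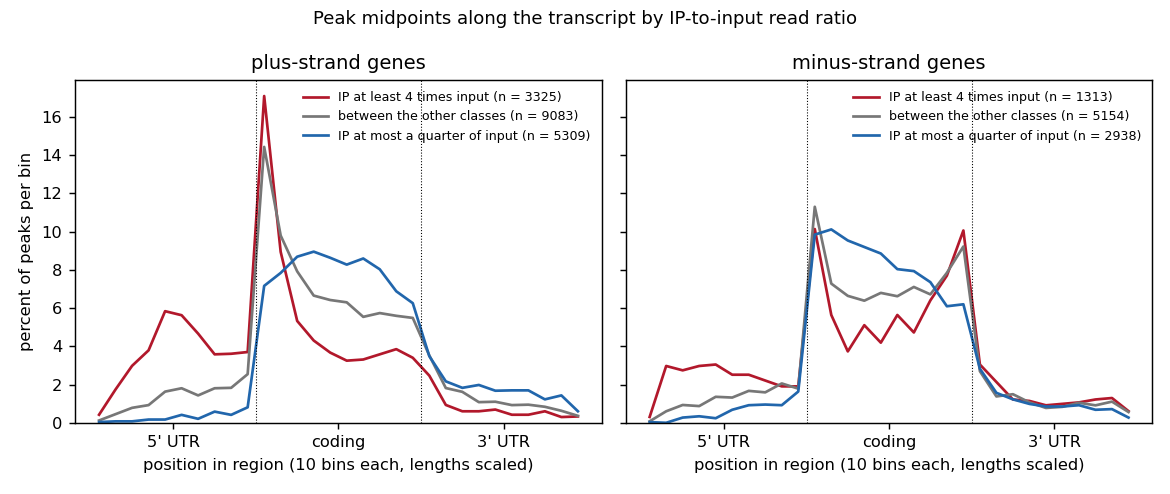
Share of peak midpoints in each of 10 bins of equal length per region (x axis, 5' UTR, coding and 3' UTR scaled to the same width; y axis, percent of peaks per bin) for plus-strand and minus-strand genes. Red lines are peaks with at least 4 IP reads per input read, blue lines those with at least 4 input reads per IP read and grey lines the rest; red lines are highest around the start codon on the plus strand, and on the minus strand they rise again at the end of the coding sequence.

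Genes on the plus strand of the genome held more of the listed peaks than genes on the minus strand. They had 18058 peaks (65.2%) in 4303 genes, against 9620 in 2966 genes, although 50.5% of protein-coding genes lie on the plus strand. A peak was listed for 42.7% of plus-strand and 30.1% of minus-strand protein-coding genes. The median score in the authors' deposited table was 4.22 for plus-strand and 2.94 for minus-strand peaks. In the 5'-most 10% of the spliced transcript the plus share was 69.1% (68.0% to 70.3%), and it was 55.6% (51.7% to 59.5%) in the 3'-most 10%.

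**Figure D3:**
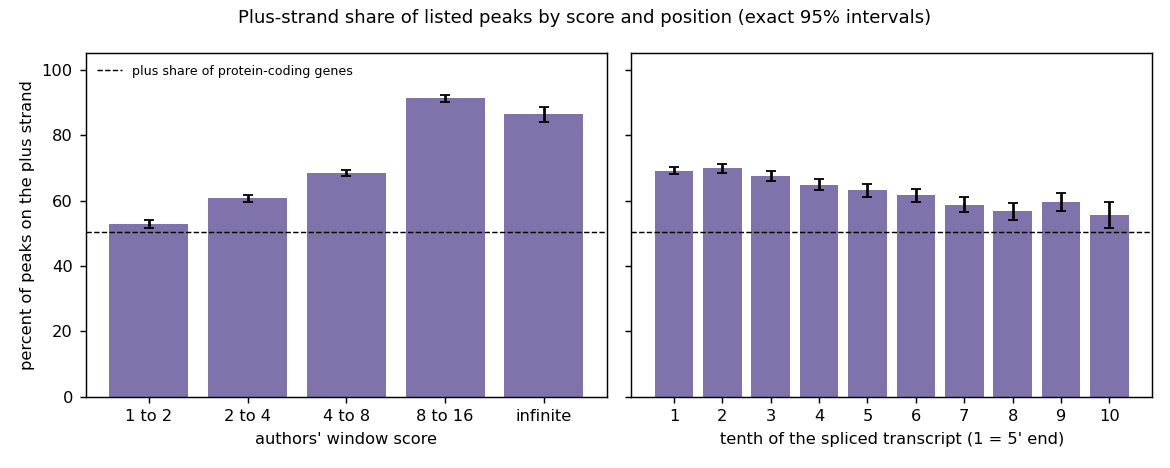
Percent of listed peaks on the plus strand (y axis, exact 95% intervals) by the score of the authors' deposited table and by position along the spliced transcript in 10 equal parts, 1 being the 5' end (x axes). The dashed line is the plus share of protein-coding genes (50.5%), and the share rises from 52.9% at scores of 1 to 2 to 91.2% at 8 to 16, is 86.5% at infinite scores and is lower toward the 3' end; 7 peaks at finite scores of 16 or more are not drawn.

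Stop codons, where m6A maps of mRNA usually show most sites, held slightly fewer peaks than random positions. Of 27122 peaks on coding transcripts, 11.2% had their midpoint within 200 nt of the stop codon, against 12.01% of random windows in the same transcripts (0.936 times; permutation of positions, p = 0.0198, two-sided, the smallest that 100 draws allow). Among peaks with at least 4 IP reads per input read the share was 9.44% against 12.4%. The direction turned with the strand: plus-strand genes had 10.8% against 12.4% (0.866 times) and minus-strand genes 12.1% against 11.3% (1.07 times; permutation p = 0.0198 for each). For the peaks with at least 4 IP reads per input read these factors were 0.576 on the plus and 1.30 on the minus strand. Within 100 nt the deficit was not past the threshold (0.957 times, permutation p = 0.0990). All of these p-values take overlapping peaks as independent and may be too small.

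The broad methylation consensus DRACH was present in 95.3% of peaks and in 95.3% of their shuffled copies (permutation of dinucleotides, p = 0.792), a share too close to saturation to separate them. Per 100 nt there were 1.85 DRACH sites in peaks and 1.92 in shuffled copies (0.961 times, permutation p = 0.0198). The narrower core GGAC was above its shuffled copies, at 0.545 against 0.481 sites per 100 nt (1.13 times, permutation p = 0.0198), and 63.4% of peaks held it against 60.3%. In peaks with at least 4 IP reads per input read GGAC rose to 0.688 per 100 nt (1.21 times the shuffled copies), and in those with at least 4 input reads per IP read it was 0.429 (1.05 times). Windows of the same transcripts outside peaks had 0.376 GGAC per 100 nt where the peaks had 0.545 (1.45 times; permutation test, p = 1e-05, the smallest it can give), but their median GC content was 48.6% against 55.0%. With that control DRACH sites were 1.01 times as frequent in peaks (permutation p = 0.0816). In peaks with at least 4 IP reads per input read, however, they were 0.838 times as frequent as in such windows, at 1.499 against 1.789 per 100 nt (permutation p = 1e-05, again the smallest possible), and 92.8% of these peaks held a site against 95.1% of the windows. GGAC went the other way in the same comparison, at 0.691 against 0.375 per 100 nt (1.84 times, permutation p = 1e-05). Median GC content was 65.3% in these peaks and 50.6% in their windows, and against shuffled copies their DRACH sites stood at 0.995 times (permutation p = 0.257).

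Of the 23 lists of protein-coding genes, 7 carried listed peaks more often than other genes and 2 less often. Chromatin regulators had a peak in 27 of 35 members (77.1% against 36.4%; Fisher's exact test, adjusted p = 9.27e-06), zinc finger genes in 253 of 509 (49.7%; adjusted p = 1.81e-08), the EGFR and MAPK pathway in 19 of 29 (65.5%; adjusted p = 0.00645), TGF-beta and SMAD in 17 of 26 (65.4%; adjusted p = 0.0115) and integrins, matrix and proteases in 22 of 37 (59.5%; adjusted p = 0.0159). Replication-dependent histones, whose mRNAs end in a stem-loop, had a peak in 5 of 71 (7.04%; Fisher's exact test, adjusted p = 1.75e-07), with HIST1H2BD and HIST1H2BN at the same 31 IP and 13 input reads, a pair of near-identical genes whose reads may be shared. Such mRNAs lack a poly(A) tail and poly(A) RNA was purified, so this low share cannot be read as low methylation. Of mitochondrially encoded genes and their look-alikes, 1 of 24 had a peak (4.17%, Fisher's exact test, adjusted p = 0.0019). That was the nuclear copy MTRNR2L8, and 0 of the 13 genes of the mitochondrial chromosome were listed. Whether that chromosome was searched for peaks was not given in the sources used here. This low share therefore cannot be read as low methylation either. The remaining lists did not pass Fisher's exact test: metastasis mediators 16 of 31 (adjusted p = 0.153), EMT 10 of 20 (0.333), angiogenesis 14 of 25 (0.113), cell junctions 12 of 23 (0.202), Hippo pathway 14 of 24 (0.0759), immediate early and short-lived regulators 14 of 31 (0.405), housekeeping 9 of 22 (0.693), cytosolic ribosomal proteins 23 of 86 (0.127) and nuclear oxidative phosphorylation 28 of 85 (0.627). Long transcripts carried peaks more often, in 56.8% of the longest quartile and 16.7% of the shortest. Matched on transcript length, the calls of zinc finger genes, writers and erasers, and histones held, whereas chromatin regulators and the EGFR and MAPK pathway both fell to an adjusted p of 0.0708, TGF-beta and SMAD to 0.193, integrins, matrix and proteases to 0.352 and mitochondrially encoded genes to 0.234.

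Several of the highest ratios named from these lists lay at 5' ends, which were not counted over the members. Over all genes with a peak, the highest peak lay in the 5' UTR for 39.3% by the authors' region column. Among integrins, matrix and proteases, the laminin-binding integrin ITGA6 had 246 IP and 3 input reads in its 5' UTR (chromosome 2, 172427555 to 172427964; 82.0, 27.7 to 400.4) and the collagen COL4A2 183 and 4 (45.75, 17.6 to 169.7). The VEGF co-receptor NRP2 reached 65.7 (31.6 to 164) in its 5' UTR, and the Notch ligand DLL4 had 21 IP and 0 input reads (at least 7). Among EMT and TGF-beta genes, SMAD3 reached 19.2 (13.9 to 27.2), the receptor tyrosine kinase AXL 17.1 (15.7 to 18.6) with 9686 and 568 reads, and TGFBR2 9.71 (4.47 to 25.1). Of the immediate early genes, JUNB had 497 IP and 19 input reads (26.2, 16.6 to 43.8) and JUN 6139 and 330 (18.6, 16.7 to 20.8). The Hippo target CYR61 reached 25.7 (21.4 to 31.2), beta-catenin (CTNNB1) 13.4 (11.6 to 15.5), and the chemokine CXCL1 9.05 (7.35 to 11.2). In peaks placed in the coding sequence or beyond, the actin-bundling gene FSCN1 reached 12.6 (9.93 to 16.2) in exon 2, and the transcription factor CEBPB had 4358 IP and 172 input reads at the end of its coding sequence and in its 3' UTR (25.3, 21.8 to 29.7). The chromatin remodeller SMARCA4 had 2776 and 198 reads in coding exon 27 (14.0, 12.1 to 16.3) and the maintenance methyltransferase DNMT1 4096 and 368 in exon 13 (11.1, 10.0 to 12.4).

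As groups, genes for ribosomal proteins and for oxidative phosphorylation had low IP-to-input ratios. Their median highest ratio per gene was 0.781 over 23 ribosomal protein genes, against 2.87 in random lists (1.30 to 5.74; permutation of list membership, adjusted p = 0.0396), and 1.00 over 28 oxidative phosphorylation genes against 2.83 (1.39 to 5.43; adjusted p = 0.0396). Single members went the other way, such as NDUFA1 with 1806 IP and 52 input reads (34.7, 26.4 to 46.7) and RPS19 with 13087 and 1160 (11.3, 10.6 to 11.99). Neither call held against random lists matched on transcript length (permutation test, adjusted p = 0.133 and 0.168), although the log2 differences stayed similar, at -1.66 after -1.88 for ribosomal proteins and -1.19 after -1.50 for oxidative phosphorylation. With the median peak of a gene in place of the highest, zinc finger genes lay above random lists (1.57 against 0.853; permutation test, adjusted p = 0.0018). By the highest peak no other list passed the permutation test: immediate early genes had a median of 6.45 (adjusted p = 0.211), integrins, matrix and proteases 5.49 (0.211), EMT 5.32 (0.572), EGFR and MAPK 3.50 (0.906), chromatin regulators 3.33 (0.906), metastasis mediators 3.27 (0.906), zinc finger genes 3 (0.906), Hippo 2.72 (0.964), sialyltransferases 2.70 (0.964), cell junctions 2.49 (0.906), histones 2.29 (0.906), angiogenesis 2.17 (0.906), housekeeping 1.57 (0.805), and TGF-beta and SMAD 1.10 (0.211).

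**Figure D4:**
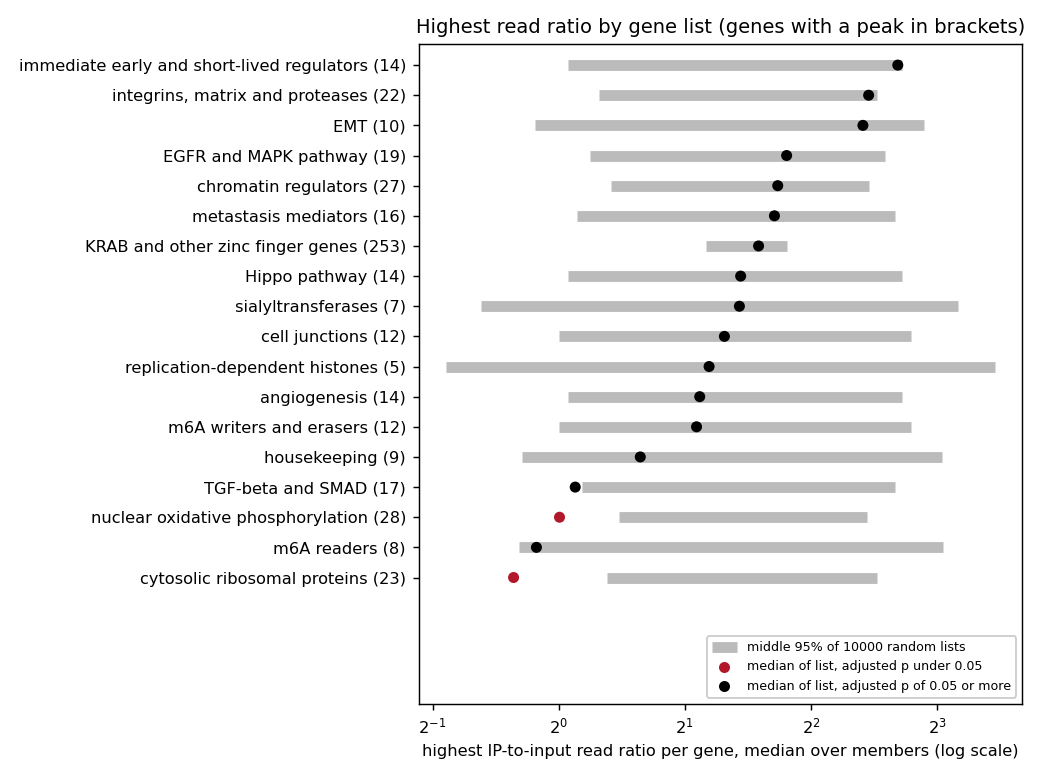
Median over members of the highest IP-to-input read ratio per gene (x axis, log scale, pseudocount of 1) for the 18 lists with at least 5 genes carrying a peak. Grey bars span the middle 95% of 10000 random lists of the same size, and the red points, ribosomal proteins and oxidative phosphorylation, lie below their bars (permutation test, adjusted p = 0.0396).

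Chromatin regulators also had the most peaks per gene, with a median of 8 in the 27 genes with a peak against 3 in random lists (permutation of list membership, adjusted p = 0.0036), and this held with lists matched on transcript length. DNMT1 had 19, SMARCA4 15 and ARID1B 10. Integrins, matrix and proteases had a median of 5.5 (permutation test, adjusted p = 0.0378), with COL4A2 at 25, ITGA6 at 19 and TIMP3 at 11. With peaks closer than 100 bp merged, the chromatin regulators still passed and the matrix list did not (permutation test, adjusted p = 0.117). The other 16 lists did not differ from random lists, the smallest adjusted p among them being 0.632.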

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

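Alternatives based on the strand, the authors' score, the fitted reference ratio, own midpoints in the enrichment by region, random lists matched on the number of peaks, and the threshold of 4 IP reads per input read outside the counts of peaks and genes were chosen after seeing the data; the others were fixed before the data were examined. No paired analysis was possible because the table holds 1 IP and 1 input count per peak without replicate values. For the same reason the test of IP against input (DESeq2, filter, pseudocount, replicate block, leaving out replicates) and the overlap between replicates were not run, and keeping only exonic peaks changed nothing because all listed peaks carry exonic classes. Of the values that answer a comparison, 83 kept direction and side of the threshold (or stayed within their interval) under an alternative, 34 moved, 36 no longer passed, 4 passed where they had not, and 8 reversed; of the other values 237 were the same and 7 newly passed. These were coverage of ribosomal proteins above the median ratio (13.95%) and at 4 IP reads per input read (3.49%) and of oxidative phosphorylation at the latter (3.53%), all lower than other genes; angiogenesis on the plus strand (81.8%); the log2 ratio of zinc finger genes by their median peak (0.65); and peaks per gene of Hippo on the plus strand (8.5) and of zinc finger genes on the minus strand (1). Peaks fell to 13838 above the median ratio, 13839 by the authors' p, 4761 (in 3160 genes) at 4 IP reads per input read and 14061 after merging, and genes to 4759 by the authors' p, as fewer peaks were admitted. The shares of 5' UTR, coding and 3' UTR were 28.1%, 59.9% and 11.97% above the median ratio, 42.1%, 47.6% and 10.3% at 4 IP reads per input read, 27.0%, 62.7% and 10.3% above the gene reference, 13.5%, 73.7% and 12.8% by midpoint, 24.0%, 64.2% and 11.8% on the plus strand, and 6.33%, 76.1% and 17.6% on the minus strand; with 1 peak per gene 5' UTR and coding were 39.3% and 46.5%. The strand difference follows in part from the authors' column reading the genome-left end. The stop codon ratio was 0.957 at 100 nt (permutation p = 0.0990) and reversed to 1.07 on the minus strand (permutation p = 0.0198). For DRACH, sites over control were 1.13 with GGAC and 1.01 against transcript windows (permutation p = 0.0816), both reversed, and 0.999 with RRACH (p = 0.970) and 0.995 at 4 IP reads per input read (p = 0.257), no longer past the threshold. The share of peaks with a site came to lie above its control with GGAC (63.4%), RRACH (91.5%), at 4 IP reads per input read (93.1%), above the gene reference (95.3%) and against transcript windows (95.2%). These count among the reversed values, although the main share did not differ from its control (permutation p = 0.792) and had no direction to turn. Above the median ratio (94.8% against 94.4%) and on the minus strand it also lay above, without passing. The difference of 3' UTR from coding peaks passed at -0.20 by midpoint, -0.26 with the authors' score, -0.39 on the plus strand and 0.43 on the minus strand. Both strand values use the authors' column, which reads opposite ends of peaks on the strands. The change of sign therefore cannot be told apart from the end that was read. List coverage had 3 lists passing when length-matched, where the percentages stayed while the background rose, or fell from 36.5% to 18.0% for mitochondrially encoded genes (study targets 100%, EGFR and MAPK 65.5%, integrins, matrix and proteases 59.5%, TGF-beta and SMAD 65.4%, chromatin regulators 77.1%, mitochondrially encoded 4.17%; adjusted p 0.0708 to 0.352). Above the median ratio, study targets (75%) and TGF-beta and SMAD (46.2%) no longer passed, each at an adjusted p of 0.163. At 4 IP reads per input read the same held for study targets (50%), writers and erasers (23.1%), EGFR and MAPK (31.03%), TGF-beta and SMAD (23.1%) and mitochondrially encoded genes (0%). On the plus strand it held for study targets (100%, against a background of 42.7% in place of 36.5%), EGFR and MAPK (77.8%) and TGF-beta and SMAD (64.7%). The minus strand had 3 lists passing, without writers and erasers (80%), integrins, matrix and proteases (37.5%), TGF-beta and SMAD (66.7%), chromatin regulators (64.3%) and mitochondrially encoded genes (12.5%). For the log2 ratio of lists, 0 passed when length-matched (ribosomal proteins -0.36, oxidative phosphorylation 0.0068), 0 with the authors' score (1.82 and 1.97), 0 on the minus strand (-0.88 and 0.0068), 1 on the plus strand (ribosomal proteins, at 0.48, did not) and 1 when matched on the number of peaks (oxidative phosphorylation, at 0.0068, did not); with the median peak of a gene oxidative phosphorylation, at -1.24, no longer passed. For peaks per gene, 1 list passed after merging, without integrins, matrix and proteases (2.5), which also missed on the plus strand (5.5), as did chromatin regulators on the minus strand (6.0). Except where a reason is given, the cause was not tested. Depth limits single peaks: with 32 IP reads at the median, the intervals of weak peaks are wide.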

Other observations

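The tests of peaks below the reference ratio of their gene and of the strands were chosen after the results were seen, and those of base composition and of consensus sites before.

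For markers of luminal breast, brain, and immune and stromal cells, no difference from other genes in carrying a peak was detected. Luminal breast markers had 3 of 15 (Fisher's exact test, adjusted p = 0.343), immune and stromal markers 3 of 15 (0.343) and brain cell markers 2 of 17 (0.087). In the neuronal tubulin gene TUBB3 a 5' UTR peak had 58 IP reads and 1 input read (58.0, 10.0 to 2330), and in SYT1, of synaptic vesicles, there were 5 IP reads and 1 input read (5.00, 0.560 to 236.5). GATA3 had 8 IP and 0 input reads, and the epithelial adhesion gene EPCAM had 7 and 0. CD68, a macrophage marker also made by other cells, had 23 and 2 (11.5, 2.84 to 100.6). Of 20 sialyltransferases 7 had a peak (Fisher's exact test, adjusted p = 1), with ST8SIA4 highest at 13.5 (5.94 to 37.9) and ST3GAL2 at 9.69 (5.78 to 17.4), above the 2.89 of ST6GALNAC5. None of 14 long non-coding RNAs had a listed peak, and 19 peaks in all lay in genes that do not code for protein. Every listed peak carried a 5' UTR, coding or 3' UTR class. The absence of these RNAs therefore cannot be read as a lack of methylation. Among zinc finger genes ZNF316 was highest, with 512 IP and 6 input reads in exon 9 (85.3, 38.9 to 233.6).

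The highest read ratios included counts that cannot be assigned with certainty. TRIM15 had 488 IP and 0 input reads in each of 8 peaks, and its neighbour TRIM10 had 487 and 0 in each of 8. S1PR3, named after its values were seen, had 21 and 0 in each of 5 peaks. These were the only genes with at least 4 peaks of identical counts, and 49 peaks reached beyond the annotated end of their gene. SP5 had 161 IP and 0 input reads (at least 53.7), MIDN 113 and 0 (at least 37.7), NFKBIE, an inhibitor of NF-kappaB, 212 and 1 (212, 37.6 to 8413), and ATRNL1 314 and 2 (157, 43.1 to 1302).

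Of the 19520 peaks in genes with at least 4 peaks, 58.7% (57.7% to 59.7%) lay below the fitted reference ratio of their gene. This share says nothing about a shallow IP library, because the reference is fitted within the gene and takes up the depth, so that explanation was left untested. In 87.9% of 2766 genes the p in the authors' deposited table lay closer to a two-sided than to a one-sided binomial p against that ratio. A candidate explanation is that windows depleted of IP reads were listed along with enriched ones. No biological explanation was tested, since the design has a single cell line without a contrast.

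Plus-strand genes held 65.2% of peaks (63.8% to 66.7% over resampled genes). The number of genes per strand does not account for this, since 50.5% of protein-coding genes lie on the plus strand. The plus share rose by 37.1 percentage points (34.5 to 39.9), from 52.9% at scores under 2 to 90.02% at 8 or more, infinite scores included, so a score that acts differently on the strands is a candidate cause. A listing that favours the genome-left end of transcripts would leave fewer plus-strand peaks at the 3' end. By midpoint the plus share was 69.1% in the 5'-most 10% of the transcript. In the 3'-most 10% it was 55.6% (50.8% to 60.4% over resampled genes). This lay narrowly above the share of genes but below the 65.2% of all peaks. The comparison with genes therefore cannot decide on this explanation. Placed by their 5' end or 3' end, peaks gave 57.9% and 60.97%, whereas the genome-left end, on which the idea arose, gave 31.3% and the genome-right end 82.5%; such placement shifts the strands in opposite directions by construction.

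The IP-to-input read ratio was highest at the 5' end, with a median log2 difference between 5' UTR and coding peaks, by midpoint, of 2.08 (1.99 to 2.22). Within 10 bins by GC content, of about equal peak number, it was 0.43 (0.30 to 0.54), so 20.7% of it remained. Base composition and position cannot be told apart for the part that went, because 5' UTR peaks are also the GC-rich ones. The remainder lay above 0 within the bins, but each bin still spans a range of GC content. The median read ratio was 1.55 at 60% to 70% GC and 6 at 70% or more. The remainder therefore cannot be told apart from base composition either. DRACH sites over shuffled copies were compared between the 25% of peaks with the highest read ratio and the lowest 25%. They were higher in the former, by 0.0761 log2 (0.0553 to 0.0992). They stood at 0.991 and 0.940 times the shuffled copies. GGAC stood at 1.20 and 1.05 times. Per 100 nt, though, DRACH was less frequent in peaks with at least 4 IP reads per input read (1.504) than in those with at least 4 input reads per IP read (2.005), and 0.838 times as frequent as in windows of the same transcripts, while GGAC was 1.84 times as frequent as there; GC content differed between these sets (65.3% against 49.5% and 50.6%), so whether consensus sites contribute to the 5' excess stays open.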
